A study of Rattus norvegicus with 23 samples.

How the data were processed

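Endothelial RNA of 23 culture inserts was analysed, in 4 groups that the sample titles name: normoxia (6 inserts), OGD/R (6), OGD/R with DMT (5) and OGD/R with DMT and BD1063 (6). Below, the last 2 are called the DMT group and the BD1063 group, and a library is named by its group and the number in its title, as in DMT 5. Each column of the deposited tables was matched to 1 sample by the library name in the labels, and 0 columns were left unused. Per the labels' protocols, total RNA was isolated on columns, poly-A RNA was enriched, strand-specific libraries were made with random priming and PCR, and single reads were taken on a NextSeq instrument. The submitters' processing notes name cutadapt 3.4, FastQC 0.11.9, STAR 2.7.10a, RSEM 1.3.3, DESeq2 1.38 and the genome build Rnor_6.0, with no role or order. How reads shared between near-identical genes were assigned, and whether strand was used in counting, is not given in the sources used here, so values of gene families with close copies (ribosomal RNA and ribosomal protein genes, for example) are uncertain in how they are divided among the copies.

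The table of counts that the authors deposited holds whole numbers for 32883 gene identifiers. It pairs each identifier with a symbol and a gene type. A name was missing for 396 identifiers and 192 names stood for several identifiers. Where a name recurred, the identifier with the highest mean count was used in the gene lists. The other deposited table is named as TPM, but within each library every value was the count divided by 1 number that was the same for all genes, so gene length was not used and the values are CPM (reads scaled to a common library total) of a read total larger than the sum of the gene counts. Whole reads were recovered from 100% of its values in every library, within 0.01 of a read, and 100% of them equalled the deposited counts. The edgeR test on the recovered reads called 4916 genes in OGD/R against normoxia, as the test on the deposited counts did. The deposited CPM-like values were therefore used only in alternatives. The gene counts held between 58.8% and 75.7% of that read total. No coordinates stand in the files and no genome of the build Rnor_6.0 was used here, so no positions are given.

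Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, robust, two-sided), with TMM library scaling and the filterByExpr default minimum of 10 counts, which left 13834 genes. All 23 libraries entered 1 fit of 4 group means with no covariates, and adjusted p-values are Benjamini-Hochberg values over the 13834 genes of each comparison, with a threshold of 0.05. Levels are CPM of the gene counts after TMM scaling, given as mean ± SD over libraries. Fold changes are on the log2 scale with their standard errors (SE). Gene lists, 36 in number, were fixed before the data were examined and tested with limma 3.58.1 (camera, preset correlation of 0.01), with Benjamini-Hochberg adjustment over the 36 lists of a comparison. Beside each call the adjusted p with an estimated correlation is given where it misses the threshold. A list score is the mean log2 CPM of a list's tested members in a library. Scores were compared by two-sided exact permutation tests over all 924 or 462 assignments, with 95% intervals from inverting the test. The smallest exact p is 0.00217, and adjusted over 36 lists 1 list alone at that value does not pass. A score that misses the adjusted threshold is thus weak evidence of no difference.

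Genes named in the text follow a rule fixed before the data were examined. For each of the first 4 comparisons it takes the 4 largest rises and the 4 largest falls among called genes with a mean of at least 4 CPM and a symbol that is not provisional, the 2 members with the smallest p of each of the 8 lists with the smallest camera p, and Cldn5, Ocln, Tjp1, Cdh5, Slc2a1 and Abcb1a. It named 72 genes, of which some are not reported here. The rule named 5_8S_rRNA for 2 identifiers of that symbol, and values are given for 1 of them. A further 27 genes were chosen after their values were seen and are marked so. Abcb1a, Pecam1, Gapdh, Cd36 and some other list members were not found under those symbols and are not analysed here.

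Alternatives planned before the data were examined were DESeq2 size factors, DESeq2 1.42.0 (Wald test), limma voom with sample weights, no filter beyond 1 read in all, a filter of at least 50 counts in at least 5 samples, the replicate number as a block, a test against a fold of 1.5 (glmTreat), the groups compared alone, limma on log2(deposited CPM + 1) and log2(deposited CPM + 0.1), with values of at least 1 in at least 5 samples, and leaving out each library in turn. Chosen after seeing the data were the recovered reads, protein-coding genes alone, and leaving out together OGD/R 5 and DMT 5, these with OGD/R 3, or these with normoxia 3 and normoxia 5. The edgeR fit was tested on simulated counts of 13834 genes, with 67, 67 and 66 genes per comparison changed 1.25-fold, 1.5-fold and 2-fold. Genes were drawn independently with their fitted spread, so shifts shared by many genes of a library were not simulated. For OGD/R against normoxia it recovered 25.4%, 73.1% and 87.9% of genes changed 1.25-fold, 1.5-fold and 2-fold, for DMT against OGD/R 22.4%, 74.6% and 93.9%, for BD1063 against DMT 22.4%, 73.1% and 86.4%, and for BD1063 against OGD/R 25.4%, 65.7% and 89.4%, with 4, 7, 8 and 8 unchanged genes called. Between libraries of a group, counts differed by a chi-square of 3.15 to 105 per degree of freedom over 55 pairs, so no pair agreed within sampling noise. Figures were drawn with matplotlib 3.10.9. Wilson 95% intervals of the shares of counts given below are within 0.00976 percentage points of the value. They cover counting error only, since reads without molecular identifiers are not independent molecules.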

Results

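Gene expression was measured by RNA sequencing in primary rat brain endothelial cells that had been cultured together with pericytes and astrocytes, a model of the blood-brain barrier. Each library came from the endothelial lysate of 1 culture insert. Inserts were kept in normoxia (n = 6), or exposed to OGD/R (oxygen-glucose deprivation followed by reoxygenation, a culture model of ischemic stroke) alone (n = 6), with N,N-dimethyltryptamine (DMT, a ligand of sigma and serotonin receptors; n = 5) or with DMT and BD1063 (a sigma receptor antagonist; n = 6). Doses and times were not given in the sources used here. Whether inserts came from separate cell isolations was not given either, so p-values measure only the spread between these inserts. Gene counts summed to between 12162759 reads (DMT 3) and 18565166 reads (normoxia 1) per library. In counts simulated for OGD/R against normoxia with genes drawn independently, the test recovered 73.1% of genes changed 1.5-fold. Only 67 genes were changed by that fold there, while 4916 were called in the real comparison. The adjusted threshold is looser where more genes change, so this share is not the sensitivity of the real comparison.

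Some libraries stood apart in the make-up of their RNA. Genes of noncoding RNA classes (ribosomal, small nuclear, small nucleolar and similar RNAs) took 2.54% of the counts of OGD/R 3 (95% Wilson interval 2.53% to 2.55%), against 0.0894% to 0.235% in the other OGD/R libraries. The share of the read total that fell in genes was 58.8% in OGD/R 3 against 71.9% to 75.2% in the other OGD/R libraries, and 62.6% in DMT 3 and 68.1% in DMT 5 against 73.2% to 75.4% in the other DMT libraries. Ribosomal protein genes took 3.50% of the counts of DMT 5, against 1.90% to 2.09% in the other DMT libraries, and 3.28% of those of OGD/R 5, against 2% to 2.44%. Transcripts coded by the mitochondrial genome took 1.81% of the counts in DMT 5 and 2.66% to 2.97% in the other DMT libraries. Mean shares of ribosomal protein genes were 2.09% ± 0.241 (SD, n = 6) in normoxia, 2.42% ± 0.451 (n = 6) in OGD/R, 2.32% ± 0.665 (n = 5) with DMT and 2.11% ± 0.151 (n = 6) with DMT and BD1063.

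**Figure D1:**
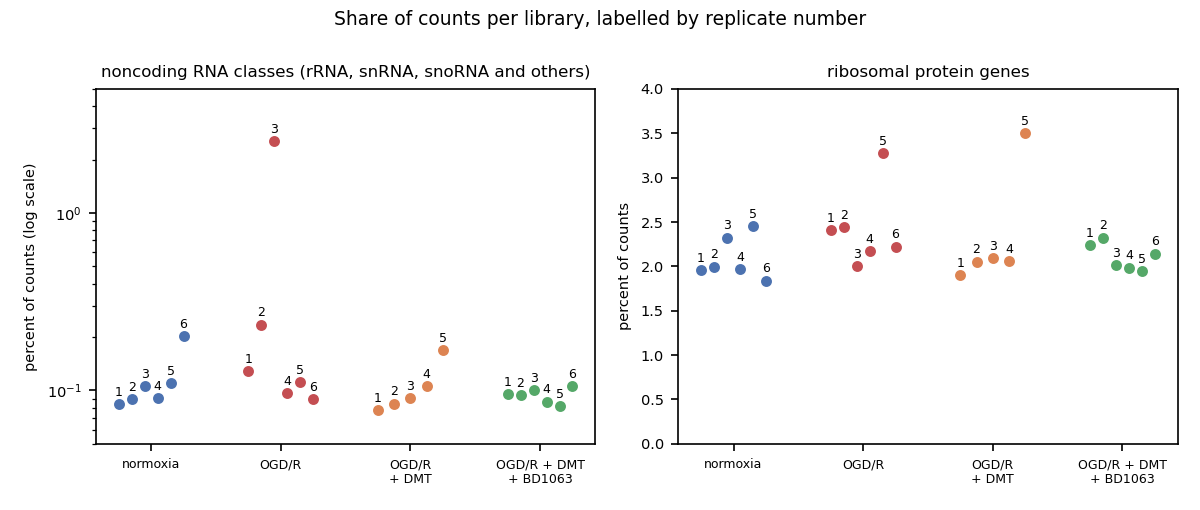
Percent of a library's gene counts in noncoding RNA classes (left, log axis) and in ribosomal protein genes (right), with 1 point per library in each of the 4 groups, numbered by replicate. OGD/R 3 stands at 2.54% on the left, and DMT 5 (3.50%) and OGD/R 5 (3.28%) stand highest on the right.

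The comparison of OGD/R with normoxia asks what deprivation and reoxygenation changed in the endothelial cells. Genes of DNA replication and cell division rose together. Of 32 cell cycle genes 30 rose and 0 fell (31 and 0 adjusted over the list alone), with a median log2 fold change of 0.61 and a camera adjusted p of 3.18e-32. Mcm5 and Mcm3, subunits of the replicative helicase, went from 74.4 ± 7.45 and 64.3 ± 6.75 CPM (mean ± SD, n = 6) to 177 ± 17.1 and 147 ± 12.8 CPM (n = 6), with a log2 fold change of 1.19 ± 0.07 (SE) for Mcm3 (adjusted p = 6.2e-12 and 1.06e-11). Genes of cholesterol export under the liver X receptor fell, with 6 of 9 lower and 0 higher (7 and 0 adjusted over the list alone; median -0.46, camera adjusted p = 8.85e-06). Pltp, the phospholipid transfer protein, fell by 1.88 ± 0.11 on the log2 scale (adjusted p = 1.06e-11) and Apoe, the main apolipoprotein made in brain, fell from 503 ± 68.0 to 157 ± 38.3 CPM (adjusted p = 2.64e-08). Cholesterol synthesis genes moved the other way: 15 of 28 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.20, camera adjusted p = 0.00103, and adjusted p = 0.252 with an estimated correlation). Cyp51, a sterol demethylase chosen after its value was seen, rose by 0.37 ± 0.06 (adjusted p = 4.69e-05), and Insig1, the sterol-regulated brake on this pathway, did not pass, at -0.06 ± 0.06. The mean cholesterol list score was 5.05 ± 0.08 in normoxia (n = 6) and 5.26 ± 0.05 in OGD/R (n = 6), higher by 0.21 (95% interval 0.12 to 0.30; exact permutation p = 0.00217, the smallest that permutations can give here, 0.00709 adjusted over 36 lists). In 6 of 6 OGD/R libraries it lay above the normoxia mean.

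Many barrier genes were lower after OGD/R. Of 27 tight and adherens junction genes 11 fell and 0 rose (12 and 0 adjusted over the list alone; median -0.16, camera adjusted p = 0.00853, and adjusted p = 0.337 with an estimated correlation). Ocln (occludin) fell from 193 ± 10.8 to 108 ± 14.8 CPM (log2 fold change -0.83 ± 0.10, adjusted p = 5.44e-07) and Tjp1, the scaffold protein ZO-1, fell from 554 ± 86.8 to 409 ± 46.0 CPM (-0.44 ± 0.13, adjusted p = 0.00952). Cldn5, the main claudin of brain endothelium, and Cdh5 (VE-cadherin) did not pass, at -0.16 ± 0.14 (adjusted p = 0.391) and -0.04 ± 0.07 (adjusted p = 0.707). Among 29 transporters and carriers 12 fell and 4 rose (14 and 5 adjusted over the list alone; median -0.22, camera adjusted p = 0.000823, and adjusted p = 0.252 with an estimated correlation). The efflux pump gene Abcg2 fell from 112 ± 7.28 to 48.0 ± 6.67 CPM, the organic anion carrier gene Slco2b1 fell by 1.08 ± 0.10 on the log2 scale, and the glucose transporter gene Slc2a1 fell by 0.22 ± 0.05 (adjusted p = 1.65e-10, 2.94e-08 and 0.0019). Slco1a4 and Slco1c1, carriers chosen after their values were seen, had log2 fold changes of -1.62 ± 0.17 and -1.39 ± 0.17. Of 16 genes of caveolae and transcytosis 10 fell and 0 rose, adjusted over the list alone as well (median -0.17, camera adjusted p = 0.000185), among them Scarb1, a lipoprotein receptor gene, at -0.75 ± 0.05 and Cavin2, of the caveolar coat, at -0.37 ± 0.05.

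Endothelial identity genes split, with 11 of 28 lower and 4 higher (12 and 4 adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.347 with an estimated correlation). Kdr, the main VEGF receptor gene, rose from 294 ± 30 to 416 ± 52.4 CPM. Among Wnt targets and co-receptors 7 of 19 fell and 0 rose, adjusted over the list alone as well (camera adjusted p = 0.0385, and adjusted p = 0.225 with an estimated correlation), a call that ended without OGD/R 5 (adjusted p = 0.0576). Of 27 basement membrane and collagen genes 17 fell and 0 rose, adjusted over the list alone as well (median -0.33, camera adjusted p = 1.1e-05, and adjusted p = 0.347 with an estimated correlation). Fbln5 and Fbln1, elastic fibre and matrix glycoprotein genes, fell by 1.60 ± 0.09 and by 0.85 ± 0.09 on the log2 scale. Markers of fibroblasts and meningeal cells, which share Fbln1, Col1a1 and Col3a1 with that list, were lower too. Of these 3 of 7 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.85, camera adjusted p = 0.0479, and adjusted p = 0.347 with an estimated correlation). Their mean score was 4.28 ± 0.30 in normoxia and 3.68 ± 0.41 in OGD/R. Col3a1, chosen after its value was seen, was at 285 ± 89.6 CPM in normoxia and 105 ± 44.3 in OGD/R. Astrocyte markers had 4 of 7 lower and 1 higher, adjusted over the list alone as well (median -0.52, camera adjusted p = 0.0438, and adjusted p = 0.151 with an estimated correlation), with scores of 3.23 ± 0.10 and 2.7 ± 0.19. The astrocyte call ended without normoxia 3, normoxia 5, OGD/R 2, OGD/R 3 or OGD/R 5 (adjusted p up to 0.0668) and the fibroblast call without normoxia 3, normoxia 6, OGD/R 1, OGD/R 3 or OGD/R 5 (up to 0.0915), with a median of -0.47 without normoxia 3. With no low-count filter the astrocyte median turned to 0.15.

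Oxygen-dependent and stress genes did not move as 1 block. Among targets of the hypoxia-inducible factor 15 of 37 were lower after OGD/R and 1 higher, adjusted over the list alone as well (median -0.16, and -0.10 without OGD/R 6; camera adjusted p = 0.00033). Ddit4, an inhibitor of mTOR signaling, fell from 146 ± 11 to 51.2 ± 13.5 CPM and Ndrg1, a hypoxia-induced gene, from 318 ± 23.1 to 181 ± 9.81 CPM (adjusted p = 1.69e-09 and 1.7e-10). Immediate early genes had 17 of 24 lower and 2 higher, adjusted over the list alone as well (median -0.44, camera adjusted p = 1.26e-05, and adjusted p = 0.0903 with an estimated correlation). Btg2, an antiproliferative gene, fell by 0.90 ± 0.06 on the log2 scale and Dusp6, a MAP kinase phosphatase gene, by 0.43 ± 0.06. Nuclear-coded genes of oxidative phosphorylation had 18 of 43 higher and 0 lower (19 and 0 adjusted over the list alone; median 0.31, camera adjusted p = 0.000131, and adjusted p = 0.573 with an estimated correlation). Of these Ndufs1 and Ndufa9, complex I subunit genes, rose by 0.36 ± 0.05 and 0.41 ± 0.07, and the list score of OGD/R 5 was 7.19 against 6.61 to 6.80 in the other OGD/R libraries. Heat shock genes had 13 of 21 higher and 4 lower, adjusted over the list alone as well (median 0.26, camera adjusted p = 0.0122, and adjusted p = 0.347 with an estimated correlation), with the mitochondrial chaperonin gene Hspd1 at 0.67 ± 0.07. Lysosomal genes had 14 of 29 lower and 1 higher, adjusted over the list alone as well (camera adjusted p = 0.012, and adjusted p = 0.347 with an estimated correlation), with Tpp1, a lysosomal peptidase gene, at -0.54 ± 0.06. Their median of -0.04 was close to 0 and lay between -0.10 and -0.05 when single libraries of these 2 groups were left out. It moved by over 1.5 times without normoxia 2, 3, 5 or 6 and without OGD/R 1, 2, 3 or 5.

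Lbp (lipopolysaccharide binding protein), C1qtnf9, Msmp and Depp1 had the largest falls among called genes with a mean of at least 4 CPM and a symbol that is not provisional. Their log2 fold changes were -2.98 ± 0.24, -2.88 ± 0.11, -2.69 ± 0.15 and -2.48 ± 0.17. Inflammatory genes went both ways. Of 27 cytokine, chemokine and leukocyte adhesion genes 8 rose and 5 fell, adjusted over the list alone as well (camera adjusted p = 0.29). The list score was higher by 0.24 (95% interval 0.09 to 0.40; adjusted permutation p = 0.0138), with 6 of 6 libraries above the normoxia mean. Csf3, the granulocyte growth factor gene, rose from 0.682 ± 0.159 to 16.7 ± 8.41 CPM (n = 6 each), the neutrophil chemokine gene Cxcl6 from 37.3 ± 5.39 to 97.0 ± 39.6 and the P-selectin gene Selp from 17.6 ± 3.47 to 43.2 ± 9.15. Vcam1 fell from 9.39 ± 1.21 to 6.32 ± 2.03. Icam1, Il6 and Ccl2 did not pass (adjusted p = 0.173, 0.491 and 0.621). The complement gene C3 rose by 1.93 ± 0.40 and Lcn2 (lipocalin 2) by 1.27 ± 0.25, with Lcn2 at 1360 CPM in OGD/R 5 against 325 to 547 CPM in the others. Cyp1a1 and Cyp1b1, targets of the aryl hydrocarbon receptor, rose by 1.35 ± 0.14 and 1.81 ± 0.30. The genes named here from Csf3 to Cyp1b1 were chosen after their values were seen.

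In total, 2608 genes were higher and 2308 lower in OGD/R than in normoxia (edgeR, adjusted p under 0.05, 4916 of 13834), with a median absolute log2 fold change of 0.40. Of these 153 rose and 241 fell at least 2-fold. In limma, 1286 were higher and 2336 lower on log2(deposited CPM + 1), and 1276 and 2292 on log2(deposited CPM + 0.1). Scaling, test and filter all differ there, so which of them moved the split between directions was not tested. On these scales the median of cholesterol genes was 0.12 on both, that of hypoxia-inducible factor targets -0.24 and -0.25, and that of lysosomal genes -0.12 on both. The median of all genes was -0.06 on both scales, against 0.01 in edgeR, so part of these moves is shared by all genes. It was 0.0009 in voom and 0.0082 under the stricter filter. These values argue against a limma test or a stricter count filter alone as the source of that shared part. Among called genes with a mean of at least 4 CPM and a symbol that is not provisional, the largest fold changes belonged to noncoding RNA genes. Of 192 noncoding RNA genes tested, 51 rose and 8 fell. Rpph1, the RNA of ribonuclease P, was at 181 CPM in OGD/R 3 against 0.249 to 4.30 CPM in the other OGD/R libraries. Rn5-8s (714 against 1.00 to 11.3 CPM) and 5_8S_rRNA (1191 against 1.31 to 14.7 CPM), ribosomal RNA genes, had log2 fold changes of 5.67 ± 1.51 and 5.44 ± 1.52 that were 0.55 and 0.05 without OGD/R 3 (adjusted p = 0.56 and 0.965). Rpph1 was then too low to be tested. With an estimated correlation the camera calls of the liver X receptor, cell cycle, caveolae and hypoxia-inducible factor lists held (adjusted p = 0.0035, 0.00964, 0.00964 and 0.0427).

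Further lists did not pass camera in OGD/R against normoxia, although the scores of several passed the permutation test. Camera adjusted p was 0.057 for complement and acute phase, 0.0704 for the NRF2 antioxidant response (14 of 31 higher and 3 lower, with the quinone reductase gene Nqo1 at 0.73 ± 0.07), 0.074 for sigma and serotonin receptors with DMT metabolism. It was 0.117 for angiogenesis and tip cell genes, of which 11 of 30 fell and 7 rose, Angpt2 being lower at -0.36 ± 0.06. It was 0.228 for matrix proteolysis, for TGF-beta and mesenchymal transition and for choroid plexus markers, 0.251 for mitochondrially coded transcripts, 0.29 for p53 targets, 0.291 for microglia and leukocyte markers and 0.351 for ATF4 targets, of which 14 of 33 rose and 8 fell. For shear-stress genes it was 0.449, for oligodendrocyte markers 0.53, for NF-kB feedback genes and the unfolded protein response 0.615, for the interferon response 0.708, for glycolysis 0.809, and for pericyte and for neuron markers 0.925. The medians of the p53 (0.02), interferon (-0.02), pericyte (-0.05) and neuron (-0.43) lists had the sign opposite to their tests. Scores were lower for shear-stress genes and matrix proteolysis (adjusted permutation p = 0.0104 for each), choroid plexus markers (0.0138) and angiogenesis genes (0.0234). They were also lower for complement (0.0297), p53 targets and TGF-beta genes (0.0325 for each), and higher for NRF2 genes (0.0468).

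**Figure D2:**
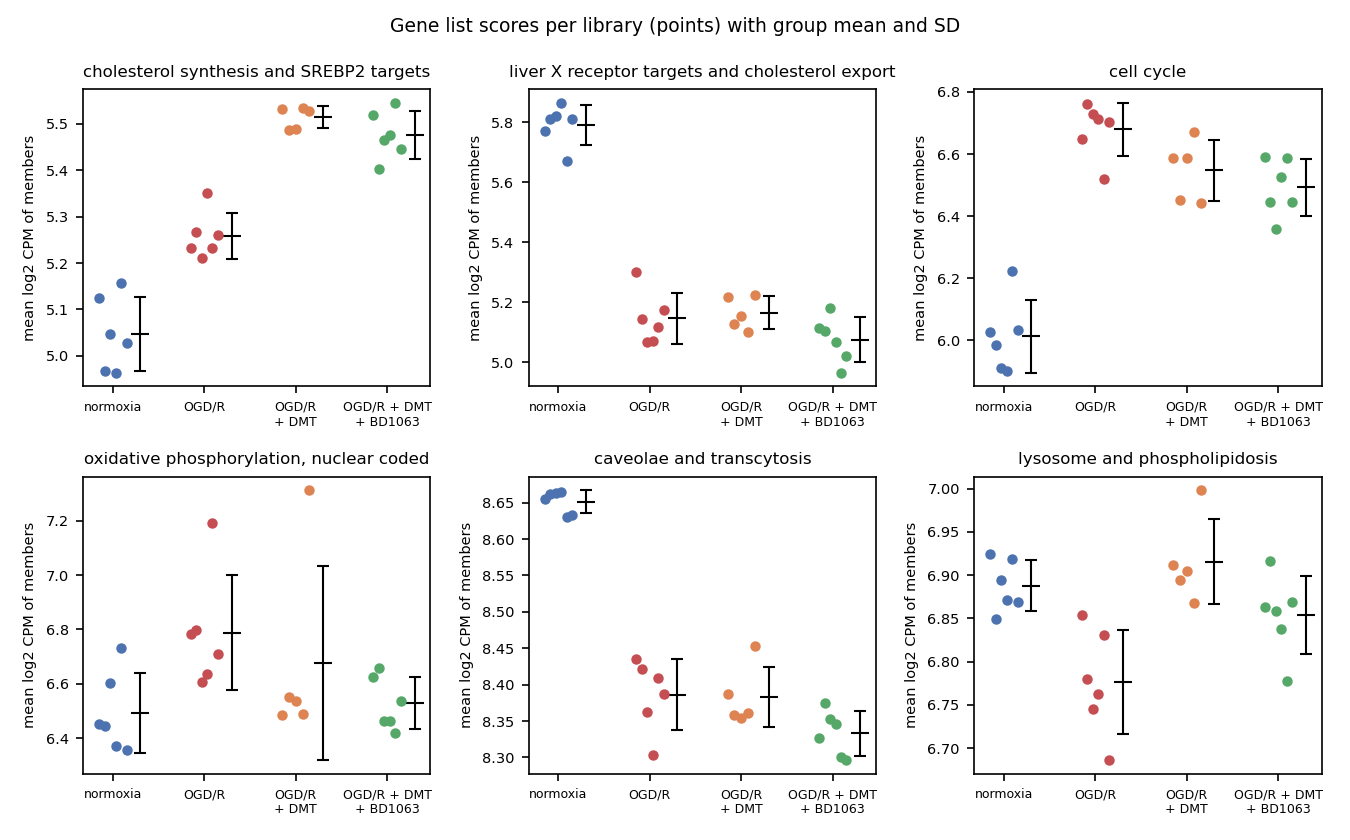
Mean log2 CPM of the members of 6 gene lists (cholesterol synthesis, liver X receptor targets, cell cycle, oxidative phosphorylation, caveolae, lysosome) in each library, with points for libraries and bars for group mean and SD. The cholesterol score was 5.05 in normoxia, 5.26 in OGD/R, 5.51 with DMT and 5.48 with DMT and BD1063.

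The comparison of DMT with OGD/R asks which genes the compound changed in deprived cells. Cholesterol synthesis was the gene group with the clearest rise. Insig1 (ENSRNOG00000006859) rose from 42.6 ± 4.61 CPM in OGD/R (n = 6) to 71.5 ± 3.28 CPM with DMT (n = 5), a log2 fold change of 0.75 ± 0.07 (SE; adjusted p = 8.53e-07). Hmgcs1 (ENSRNOG00000016552), the HMG-CoA synthase gene, rose from 118 ± 7.81 to 162 ± 5.02 CPM (0.46 ± 0.06, adjusted p = 6.93e-05). Of 28 cholesterol genes 6 rose and 0 fell (19 and 0 adjusted over the list alone; 15 and 0 without DMT 5, and 11 and 0 without DMT 5 and OGD/R 5), with a median of 0.25 and a camera adjusted p of 1.15e-28 (adjusted p = 0.000266 with an estimated correlation). Fdft1, Cyp51 and Msmo1, enzymes of the sterol branch chosen after their values were seen, rose by 0.33, 0.37 and 0.41. The list score was 5.51 ± 0.02 with DMT (n = 5) against 5.26 ± 0.05 in OGD/R (n = 6), higher by 0.26 (95% interval 0.20 to 0.31; exact permutation p = 0.00217, the smallest that permutations can give here, 0.039 adjusted over 36 lists). In 5 of 5 DMT libraries it lay above the OGD/R mean.

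Lysosomal genes also moved up with DMT. Of 29 genes 3 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.13, camera adjusted p = 4.02e-09, and adjusted p = 0.0638 with an estimated correlation). They were Gpnmb, a lysosomal stress glycoprotein gene (14.6 ± 3.78 to 25.7 ± 7.54 CPM, 0.81 ± 0.18, adjusted p = 0.0407), Neu1, a sialidase gene (0.34 ± 0.07, adjusted p = 0.0227), and Tpp1 (0.30 ± 0.06, adjusted p = 0.0364). Flcn (folliculin, a regulator of lysosomal nutrient signaling) rose by 0.61 ± 0.07 and Ulk1, an autophagy kinase gene, by 0.40 ± 0.09. Both were chosen after their values were seen. Of p53 targets and apoptosis genes 2 of 23 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.000975, adjusted p = 0.00843 with an estimated correlation; median 0.12, and 0.08 without DMT 5). The p53 call ended without OGD/R 3, OGD/R 5 and DMT 5 together (adjusted p = 0.0621, median 0.07). The 2 genes were Gdf15, a stress-induced cytokine gene, from 12.5 ± 3.17 to 25.1 ± 4 CPM (1.01 ± 0.15, adjusted p = 0.00137), and Bcl2l11, the gene of the apoptosis activator BIM (0.39 ± 0.08, adjusted p = 0.0305). Among hypoxia-inducible factor targets 2 of 37 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.08, camera adjusted p = 0.000154, adjusted p = 0.0332 with an estimated correlation). Of the scores of these lists that of p53 targets passed the permutation test (adjusted p = 0.039), and those of lysosomal genes (0.052) and hypoxia-inducible factor targets (0.203) did not. The lysosomal score was higher by 0.14 (95% interval 0.06 to 0.22; exact permutation p = 0.00433 before adjustment). The 2 hypoxia-inducible factor targets were Ndrg1 (181 ± 9.81 to 237 ± 15.0 CPM, adjusted p = 0.00223) and the histone demethylase gene Kdm4b (0.32 ± 0.07, adjusted p = 0.0285). Uap1l1 rose from 5.6 ± 1 to 11.7 ± 0.939 CPM (1.07 ± 0.11, adjusted p = 1.26e-05), and the vessel-destabilizing ligand gene Angpt2 from 543 ± 40.2 to 673 ± 42.4 CPM (adjusted p = 0.0165). The largest falls among called genes with a mean of at least 4 CPM and a symbol that is not provisional were those of Igfbp5, an IGF binding protein gene (8.93 ± 3.83 to 3.79 ± 1.47 CPM, -1.23 ± 0.27), Cuedc2 (-0.46 ± 0.09), the interferon-induced GTPase gene Gbp2 (-0.45 ± 0.08) and Cd300e (-0.42 ± 0.07). Calls of Gpnmb, Igfbp5, Cuedc2, Bcl2l11, Kdm4b, Neu1, Tpp1, Angpt2 and Ulk1 ended in 1 or more fits without OGD/R 2, 3, 5 or 6 or DMT 1, 2, 3 or 4 (adjusted p up to 0.14).

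Several lists shifted with DMT without a called member when all libraries were used. Without DMT 5, 12 oxidative phosphorylation, 8 heat shock and 5 cell cycle genes were called lower and 1 immediate early gene higher. Without OGD/R 5 as well these were 6, 5, 4 and 2, without OGD/R 3 too 7, 4, 2 and 2, and without DMT 5, OGD/R 5, normoxia 3 and normoxia 5 14, 8, 9 and 3. The scores of these lists did not pass the permutation test (adjusted p = 0.244 for cell cycle, 0.252 for heat shock and pericyte, 0.249 for immediate early and 0.831 for oxidative phosphorylation genes). Cell cycle genes had 0 of 32 called (0 higher and 6 lower adjusted over the list alone) but a median of -0.12 and a camera adjusted p of 2.52e-07 (adjusted p = 0.312 with an estimated correlation), with Mcm3 at -0.30 ± 0.07 (adjusted p = 0.0559). Heat shock genes had 0 of 21 called (0 higher and 3 lower adjusted over the list alone; median -0.14, and -0.09 without OGD/R 4; camera adjusted p = 0.00132, and adjusted p = 0.312 with an estimated correlation). Of 24 immediate early genes 0 were called (1 higher and 0 lower adjusted over the list alone; median 0.16, camera adjusted p = 0.00697, adjusted p = 0.312 with an estimated correlation, and 0.0616 without OGD/R 3, OGD/R 5 and DMT 5). Pericyte and smooth muscle markers, 0 of 11 called by either adjustment, had a median of -0.47 (camera adjusted p = 0.00132, adjusted p = 0.204 with an estimated correlation, and 0.204 without DMT 5), with scores of 2.12 ± 0.34 in OGD/R and 1.71 ± 0.36 with DMT. Their median was -0.27 under the stricter filter, where the call ended (adjusted p = 0.0696), and on log2(deposited CPM + 1). The call also ended in voom (adjusted p = 0.181). Oxidative phosphorylation genes, 0 of 43 called by either adjustment, had a median of -0.08 (camera adjusted p = 0.00296, and adjusted p = 0.782 with an estimated correlation). That median ran from -0.27 without DMT 5 to 0.00 without OGD/R 5, and the call ended without OGD/R 5, DMT 1 or DMT 4 (adjusted p up to 0.597). It moved by over 1.5 times without OGD/R 4, without OGD/R 5 and without each of the 5 DMT libraries. The list score of DMT 5 was 7.31 against 6.49 to 6.55 in the other DMT libraries.

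With all libraries, junction and transporter genes were not called as changed by DMT, and without DMT 5 1 of each was higher (medians 0.08 and 0.06). Without DMT 5, OGD/R 5, normoxia 3 and normoxia 5 it was 2 and 1, and without DMT 5 and OGD/R 5, or these and OGD/R 3, 0 and 0. Of 27 junction genes and 29 transporter genes 0 passed edgeR by either adjustment (camera adjusted p = 0.482 and 0.717), as did 0 of 27 cytokine and adhesion genes (camera adjusted p = 0.0988; 1 lower without DMT 5). Ocln was at 108 ± 14.8 CPM in OGD/R (n = 6) and 119 ± 22.1 CPM with DMT (n = 5), a log2 fold change of 0.14 ± 0.10 (adjusted p = 0.651). Tjp1 was at 0.12 ± 0.13, Cldn5 at 0.11 ± 0.15, Cdh5 at 0.01 ± 0.08 and Slc2a1 at -0.02 ± 0.05. These rested on DMT 5: without it Ocln was at 0.25 and passed (adjusted p = 0.0435), Tjp1 was at 0.26, Cldn5 turned to -0.10, Cdh5 was at 0.10 and Slc2a1 at -0.06. In DMT 5 the levels of Ocln, Tjp1 and Cdh5 were 80.6, 266 and 1567 CPM against 124 to 137, 462 to 542 and 2100 to 2271 CPM in the other DMT libraries, while Cldn5 was at 2902 against 1575 to 1646 CPM. Aldoc, an astrocyte-enriched glycolysis gene chosen after its value was seen, rose by 0.53 ± 0.12 (a call that ended in some fits without 1 library, adjusted p up to 0.108), and the astrocyte marker list did not pass (camera adjusted p = 0.0616).

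Between DMT and OGD/R edgeR called 68 genes, 45 higher and 23 lower with DMT, with 1679 at an unadjusted p under 0.05. The count was 1083 without DMT 5, and 30, 35 and 26 without OGD/R 2, 3 and 6, and 26, 37, 26 and 27 without DMT 1, 2, 3 and 4. At least 68 genes were called in 4 of 100 regroupings of these libraries, the real one among them. Chance is thus not clearly excluded for this count. DESeq2 called 264, limma voom with sample weights 729 (278 higher, 451 lower), and the edgeR test of these 2 groups alone 4. On log2(deposited CPM + 1) and on log2(deposited CPM + 0.1) limma called 5, and the test against a 1.5-fold change 0. The genes called on the deposited CPM scales were Insig1, Hmgcs1, Uap1l1, Flcn and Gdf15, and the first 4 of these in the test of the 2 groups alone. They kept their calls whichever library was left out (highest adjusted p = 1.03e-05, 0.000539, 9.72e-05, 0.000394 and 0.00744), as did Ndrg1, Cyp51, Fdft1, Msmo1, Gbp2 and Cd300e.

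**Figure D3:**
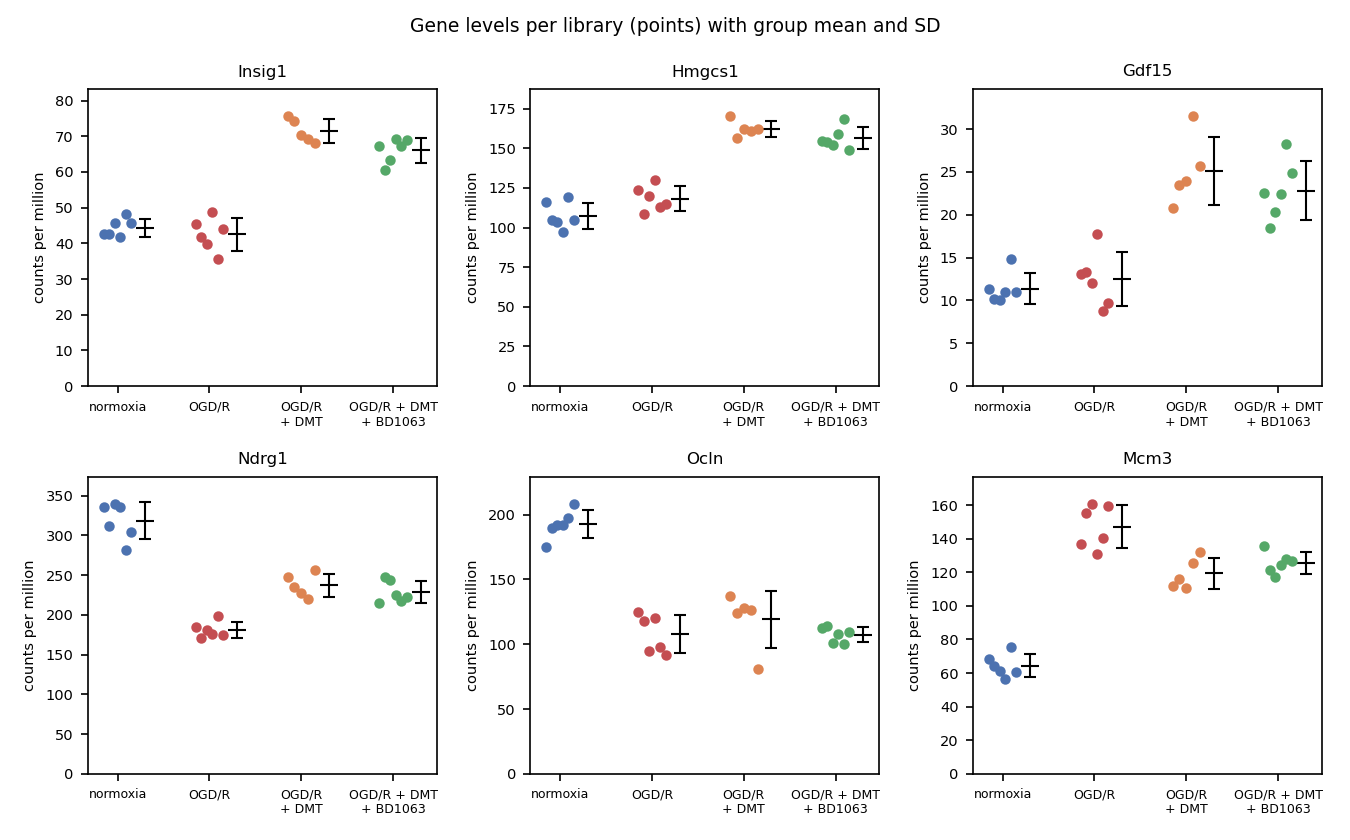
CPM of Insig1, Hmgcs1, Gdf15, Ndrg1, Ocln and Mcm3 in each library of the 4 groups, with points for libraries and bars for group mean and SD. Insig1 was at 42.6 in OGD/R, 71.5 with DMT and 66.1 with DMT and BD1063, and Ocln at 193 in normoxia, 108 in OGD/R, 119 with DMT and 107 with DMT and BD1063.

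Adding BD1063 to DMT asks which changes were altered when the sigma receptor antagonist was present. No group was given BD1063 without DMT, so effects of BD1063 itself cannot be told apart from blocking of DMT. No gene passed edgeR (0 of 13834, smallest adjusted p = 0.664, 1005 at an unadjusted p under 0.05), limma voom with sample weights called 0, and DESeq2 called 1, Mcam, an endothelial adhesion molecule gene (0.18, adjusted p = 0.0471). In counts simulated for this comparison the test found 22.4% of genes given the smallest change, 73.1% of those changed 1.5-fold and 86.4% of those changed 2-fold. These counts hold no shift shared by many genes, such as that of DMT 5, so the shares are not those of the real libraries. Genes called with DMT had a median absolute log2 fold change of 0.38, so changes of that size go partly unseen. Genes raised by DMT did not pass against it. Insig1 was at 66.1 ± 3.46 CPM with BD1063 (n = 6) against 71.5 ± 3.28 CPM with DMT alone (n = 5; log2 fold change -0.11 ± 0.07, adjusted p = 0.664). Hmgcs1 was at -0.06 ± 0.06 and Gdf15 at -0.14 ± 0.14. Cholesterol genes had a median of -0.05 (camera adjusted p = 0.35). Their score was 5.48 ± 0.05 with BD1063 and 5.51 ± 0.02 without (difference -0.04, 95% interval -0.10 to 0.02, exact permutation p = 0.16, 0.641 adjusted over 36 lists, with 2 of 6 libraries above the DMT mean). Of the barrier genes, Ocln was at -0.15 ± 0.10, Tjp1 at 0.14 ± 0.13, Cldn5 at -0.31 ± 0.15 and Cdh5 at 0.13 ± 0.08. Without DMT 5 these were -0.26, 0.00, -0.10 and 0.04.

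A few lists passed camera between BD1063 and DMT without a called gene, and each of their calls ended without DMT 5. The scores of these 5 lists did not pass (adjusted permutation p from 0.156 to 0.864). In this comparison 1 list alone could not pass that adjustment, even at the smallest exact p. The unfolded protein score was lower with BD1063 by 0.06 (95% interval 0.01 to 0.11 lower; exact permutation p = 0.00433 before adjustment). It ran from 7.13 to 7.21 with BD1063, just below the lowest DMT library. Oxidative phosphorylation genes had a median of -0.18 (camera adjusted p = 2.38e-06, and adjusted p = 0.851 with an estimated correlation), which was 0.02 without DMT 5 (adjusted p = 0.779), with Ndufa9 at -0.18 ± 0.07 and Sdha, of complex II, at -0.14 ± 0.06. Medians of lysosomal genes (-0.07), interferon response genes (-0.10) and genes of the unfolded protein response (-0.08) were lower and that of angiogenesis and tip cell genes (0.04) higher, each at a camera adjusted p of 0.0321 (adjusted p = 0.808, 0.667, 0.667 and 0.667 with an estimated correlation). Adjusted over the list alone, 0 genes passed in the first 4 of these lists and 1 was higher among the angiogenesis genes. Without DMT 5 their adjusted p was 0.102, 0.134, 0.134 and 0.134, with medians of -0.04, -0.05, -0.02 and 0.01. The lysosome call also ended without DMT 1 or BD1063 5, and the interferon call without DMT 1, 2 or 4 or BD1063 3 or 5. So did the unfolded protein call without DMT 1 or 4 or BD1063 2 or 3, and the angiogenesis call without DMT 1 or 4 or BD1063 5 (adjusted p up to 0.134). On the 2 scales of the deposited CPM the medians of the lysosomal (0.04 and 0.04), interferon (0.02 and 0.02) and unfolded protein (0.03 and 0.03) lists turned positive, where the median of all genes was 0.09 and 0.10. The angiogenesis median was then 0.15 and 0.16.

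Cells given DMT and BD1063 were also compared with OGD/R alone. Cholesterol synthesis genes were higher, with 11 of 28 called and 0 lower (18 and 0 adjusted over the list alone; median 0.21, camera adjusted p = 1.89e-14, adjusted p = 0.0142 with an estimated correlation). Insig1 rose by 0.63 ± 0.06 (adjusted p = 9.52e-06) and Hmgcs1 by 0.40 ± 0.05 (adjusted p = 0.00041). The list score was higher by 0.22 (95% interval 0.15 to 0.28; exact permutation p = 0.00217, the smallest that permutations can give here, 0.039 adjusted over 36 lists), with 6 of 6 libraries above the OGD/R mean. The scores of the other lists that passed camera here did not pass. Their adjusted permutation p was 0.0649 for cell cycle, oxidative phosphorylation, heat shock and NRF2 genes, 0.0682 for hypoxia-inducible factor targets and immediate early genes, 0.0952 for lysosomal and 0.101 for angiogenesis genes. For p53 targets the score passed (0.039) and camera did not (0.0623). Gdf15 (12.5 ± 3.17 to 22.8 ± 3.46 CPM), Uap1l1 (0.88 ± 0.11) and Gpnmb (0.79 ± 0.17) rose as well, as did Ndrg1 (0.34 ± 0.06), Kdm4b (0.28 ± 0.06) and Angpt2 (0.37 ± 0.06). Hypoxia-inducible factor targets had 3 of 37 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.07, camera adjusted p = 0.0113, and adjusted p = 0.25 with an estimated correlation). Cell cycle genes had 10 of 32 lower and 0 higher (21 and 0 adjusted over the list alone; median -0.22, camera adjusted p = 6.77e-09, and adjusted p = 0.531 with an estimated correlation), with Mcm7 at -0.33 ± 0.08 and the mitotic kinase gene Aurka at -0.32 ± 0.07. Oxidative phosphorylation genes had 5 of 43 lower and 0 higher (13 and 0 adjusted over the list alone; median -0.25, and -0.16 without OGD/R 5; camera adjusted p = 6.33e-10, and adjusted p = 0.632 with an estimated correlation), with Ndufs1 at -0.24 ± 0.05. The list score of OGD/R 5 stood at 7.19 against 6.61 to 6.80. Heat shock genes had 4 of 21 lower and 0 higher (8 and 0 adjusted over the list alone; camera adjusted p = 0.00872, and adjusted p = 0.63 with an estimated correlation), with Hspd1 at -0.26 ± 0.07. Calls of Gpnmb (without BD1063 3, adjusted p = 0.0513), Ndufs1 (BD1063 3, 0.0533), Kdm4b (BD1063 3 or 5, up to 0.0613), Mcm7 and Aurka (OGD/R 2, BD1063 3 or 5, up to 0.067 and 0.0656) and Hspd1 (OGD/R 2, 5 or 6, BD1063 3, 4, 5 or 6, up to 0.0872) ended in some fits.

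Other lists passed camera between BD1063 and OGD/R, and the calls of lysosomal, immediate early and NRF2 genes rested on single libraries. Angiogenesis and tip cell genes had 1 of 30 higher and 0 lower by either adjustment (median 0.08, and 0.05 without BD1063 5; camera adjusted p = 0.0221, and adjusted p = 0.63 with an estimated correlation). Lysosomal genes had 4 of 29 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.06, camera adjusted p = 0.0237, and adjusted p = 0.632 with an estimated correlation), with Tpp1 at 0.34 ± 0.06 and Gaa, the acid glucosidase gene, at 0.27 ± 0.05. This call ended without OGD/R 6 or BD1063 2 (adjusted p up to 0.099, median down to 0.03). Immediate early genes had 1 of 24 higher and 0 lower (3 and 0 adjusted over the list alone; median 0.12, camera adjusted p = 0.0364, and adjusted p = 0.631 with an estimated correlation). That call was lost without OGD/R 1, 2 or 3 or BD1063 2 or 4 (adjusted p up to 0.0623), with a median of 0.08 without OGD/R 2 and without BD1063 5. Genes of the NRF2 response had 2 of 31 lower and 0 higher (3 and 0 adjusted over the list alone; median -0.13, camera adjusted p = 0.0412, and adjusted p = 0.63 with an estimated correlation), a call lost without OGD/R 1, 4 or 5 or BD1063 2 or 4 (adjusted p up to 0.133). The smooth muscle gene Tagln (transgelin) fell from 207 ± 44.3 to 117 ± 29.4 CPM (-0.82 ± 0.16, adjusted p = 0.0104). The list of pericyte and smooth muscle markers did not pass (camera adjusted p = 0.0623). Among junction and transporter genes 0 of 27 and 0 of 29 passed in edgeR by either adjustment (camera adjusted p = 0.369 and 0.235). The largest falls among called genes with a mean of at least 4 CPM and a symbol that is not provisional were those of noncoding genes. They were Rpph1, 5S_rRNA, Metazoa_SRP and Rn5-8s. In OGD/R 3 these stood at 181, 204, 82.7 and 714 CPM, against at most 4.30, 2.36, 1.95 and 11.3 CPM in the other OGD/R libraries. Without OGD/R 3 the call of Rn5-8s ended (adjusted p = 0.529).

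In all, 257 genes were higher and 478 lower with BD1063 and DMT than in OGD/R (735 in edgeR, 3438 at an unadjusted p under 0.05). DESeq2 called 1297 (573 and 724), limma voom 1650, and the edgeR test of these 2 groups alone 1500 (734 and 766). The count was 108, 288, 358 without OGD/R 2, 5 and 6, and 416, 76, 142, 76 and 259 without BD1063 2, 3, 4, 5 and 6. It was 485 without BD1063 1. On log2(deposited CPM + 1) 506 were higher and 17 lower, and on log2(deposited CPM + 0.1) 473 and 14. Scaling, test and filter differ together there, and their shares in the move of this split were not separated. On these scales the median of all genes was 0.10 and 0.11 (0.09 and 0.10 for BD1063 against DMT). For BD1063 against OGD/R it was -0.0077 in voom and -0.0114 under the stricter filter. These values argue against a limma test or a stricter count filter alone as the source of the shifted median. On log2(deposited CPM + 1) the median of cell cycle genes was -0.10, that of oxidative phosphorylation genes -0.13 and that of heat shock genes -0.03, while that of NRF2 genes turned to 0.01. Medians of hypoxia-inducible factor (0.17), lysosomal (0.17) and angiogenesis genes (0.20) were higher. Insig1, Hmgcs1, Gdf15, Uap1l1, Ndrg1, Angpt2, Tpp1, Gaa and Tagln kept their calls whichever library was left out.

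Against normoxia, 1765 genes were higher and 1519 lower with DMT (3284 in edgeR), and 1809 higher and 1827 lower with DMT and BD1063 (3636). On log2(deposited CPM + 1) the splits were 686 and 1413 with DMT and 1571 and 1024 with BD1063, and on log2(deposited CPM + 0.1) 683 and 1375, and 1556 and 989. The median of all genes on these scales was -0.05 and -0.06 with DMT, and 0.05 on both with BD1063. Limma voom called 5886 with BD1063.

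Genes called with DMT often moved the other way in OGD/R. Of the 68 genes, 49 were called in OGD/R against normoxia in the opposite direction and 8 in the same direction, where independent lists of these sizes would share 11.8 and 12.3. Both comparisons use the OGD/R libraries. When those libraries were split between the comparisons, a median of 33.5 genes were called with DMT over 20 splits and a median of 10 (range 2 to 86) were opposite, where independent lists would share 4.22. Across genes, which are not independent replicates, fold changes correlated at -0.54 (covariance -0.077; simulated -0.48 and -0.015; split -0.15, range -0.30 to 0.05, covariance -0.019). The 49 included Ndrg1 (-0.82 ± 0.06 in OGD/R and 0.39 ± 0.06 with DMT), Angpt2 (-0.36 ± 0.06 and 0.31 ± 0.06), Kdm4b, Tpp1 and Bcl2l11 (lower, then higher), and Gbp2 and Cd300e (higher, then lower), while Cyp51 and Gpnmb were higher in both. The count ranged from 15 without DMT 1 to 803 without DMT 5 over 17 fits that left out 1 library each.

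For BD1063 against DMT, 0 of the 68 genes were called in the opposite direction, since edgeR called 0 genes there (DESeq2 and limma voom gave 0 opposite calls too). Fold changes of the comparisons, which share the DMT libraries, correlated across genes at -0.10 (covariance -0.0062), against -0.56 (covariance -0.019) in simulated unchanged groups and 0.15 (range -0.19 to 0.42, covariance 0.015) with the DMT libraries split. Of the 68 genes called with DMT, 52 were called in the same direction in BD1063 against OGD/R and 0 in the opposite direction, where independent lists would share 1.63 and 1.98. With the shared OGD/R libraries split, a median of 6 (range 3 to 12) were the same. The correlation of fold changes was 0.83 (covariance 0.092; simulated 0.47 and 0.015; split 0.26, covariance 0.028).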

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

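Of the tests in this part, the splits of samples for every comparison but DMT against OGD/R were planned before the results were seen, and all other tests were chosen after. In a group of 5 or 6 libraries, a library stood apart when its gap to the nearest of the others, divided by the range of the group, passed Dixon's 95% value. Chance alone marks about 1 in 20 groups. Of 560 groups tested, 73 had such a library, and 24 of these were DMT 5, 13 normoxia 5, 7 OGD/R 3, 5 OGD/R 5 and 5 normoxia 6. The groups are not independent, since genes move together.

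Noncoding RNA stood apart in OGD/R 3, with 2.537% of gene counts and 58.77% of the read total in genes. In this library 5_8S_rRNA was at 1191, 5S_rRNA at 203.6, Metazoa_SRP at 82.73, Rn5-8s at 713.8 and Rpph1 at 180.8 CPM. Normoxia 6 stood above its group in the same classes at lower levels, with a share of 0.2028%, and 5_8S_rRNA at 14.21, 5S_rRNA at 3.49, Rn5-8s at 6.233 and Rpph1 at 2.057 CPM. With OGD/R 3, the 51 noncoding genes called higher had a median log2 fold change of 3.06 against normoxia. Without it the median was 0.5274 (95% interval 0.37 to 0.59) over the 45 still tested, with 13 of 45 still called higher. The size of the rise thus rested mostly on this library. The bound set for RNA outside the poly-A fraction in OGD/R 3 as the whole source was a median under 0.5. It was missed by less than the spread. The genes were picked as higher in these same data with OGD/R 3, and those too low to test without it were left out. The interval also treats near-identical RNA genes as independent. The median thus cannot decide whether OGD/R 3 is the whole source, and this stays open. A response of the whole group stays open too: in the share of noncoding RNA 2 of 6 OGD/R libraries lay above the highest normoxia library, and 4 without normoxia 6. An interval above 0 for genes picked as higher is no separate evidence for such a response.

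DMT 5 stood apart in many values, highest in its group in the share of ribosomal protein genes (3.504%) and lowest in that of mitochondrial transcripts (1.807%). Its list scores were lowest for transporters (4.4), Wnt targets (4.726), complement (3.087), matrix proteolysis (5.328) and basement membrane (7.087), and highest for glycolysis (7.313), oxidative phosphorylation (7.311), the interferon response (4.36) and the unfolded protein response (7.319). Gene levels in CPM were lowest for Cdh5 (1567), Notch1 (109.4), Ocln (80.62) and Tjp1 (266), and highest for Cldn5 (2902), Dnaja1 (379.4), Hspd1 (239.1), Mcm7 (156.8), Pdia6 (695.7), Sdha (206.1), Sqstm1 (415), 5S_rRNA (1.784) and Metazoa_SRP (1.372). OGD/R 5 stood apart in some of the same values, with the ribosomal protein share at 3.28% and the oxidative phosphorylation score at 7.191. It was also highest in Lcn2 (1360) and lowest in Kdm4b (37.04) and Ulk1 (21.87).

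Between DMT and OGD/R, 68 genes were called with DMT 5 and 1083 without it. A candidate explanation is a shift of DMT 5 along an axis of ribosomal protein genes, tested on genes that do not code for ribosomal proteins. Their deviations in DMT 5 from the other DMT libraries correlated at 0.643 with their slopes on the ribosomal protein share within the other 3 groups, and at 0.5686 when OGD/R 5 was left out of the slopes, against a bound of 0.5. The other DMT libraries had -0.48 to -0.21, where the mean they were set against holds DMT 5, and -0.22 to 0.21 with DMT 5 left out of it. A wrong label on an OGD/R sample is argued against by the cholesterol score of DMT 5, 5.5271, above the highest OGD/R library (5.35). Added cells of other types are argued against for pericytes, astrocytes, microglia and fibroblasts, as 0 of 4 marker lists stood above the other DMT libraries in DMT 5. All 4 scores were the lowest there, so a smaller share of such cells is not argued against and was not tested. Whether the shift arose in the culture or in preparing the RNA stays open, and no biological explanation was tested.

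Cholesterol synthesis genes rose with DMT, and technical explanations were set against an effect of the compound. A source in OGD/R 5 and DMT 5 is argued against by a camera adjusted p of 5.6e-18 without them. Library scaling moves all genes alike, and the list's median stood 0.25 from that of all genes, with a lower 95% bound of 0.177. That bound treats the list's genes as independent. Camera had already picked the list by its contrast with other genes in the same data, so this check could not fail and is no separate evidence. An effect of DMT on sterol synthesis stays open as a hypothesis, found and tested on the same data. That BD1063 takes back the whole rise of 0.26 in the score is argued against by the lower bound of the difference between the BD1063 and DMT groups, -0.0957, and a smaller loss stays open. Without a group given BD1063 alone, this does not decide whether sigma receptors take part in the rise.

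Other groupings of the same libraries were counted over 100 splits per comparison, drawn from 462 and including the real one. For OGD/R against normoxia 1 split, the real one, had as many as 4916 genes (highest other 2585). For BD1063 against OGD/R 1 had as many as 735 (highest other 1). For DMT against normoxia 1 had as many as 3284 (1499), and for BD1063 against normoxia 1 had as many as 3636 (1107). In each, 1 of 100 is the smallest share such a draw can give. A random grouping of these inserts is argued against there, while variation between cell isolations is not covered by such splits. For DMT against OGD/R 4 of 100 had as many as 68 genes (3 of 80 in a first draw, which was then extended). This share lies under 0.05 by less than the error of such a draw, so chance is not clearly excluded. The highest other split called 2220 genes. It put DMT 2 and DMT 5 with OGD/R 1, 2 and 5, which points to a structure of the samples other than the groups. DMT 5 and OGD/R 5, 2 and 1 had the highest ribosomal protein shares of these groups (3.50%, 3.28%, 2.44% and 2.41%). The next was 2.22% in OGD/R 6, and DMT 2 was lower, at 2.05%. Whether the ribosomal protein axis is that structure was not tested. For BD1063 against DMT 0 genes were found, which all 100 splits must reach (highest other 1), so the splits say nothing about chance there.

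In normoxia 5 the share of the 10 most abundant genes was 6.608% and the basement membrane score 7.968, the lowest of its group. Gene levels there were highest in CPM for Angpt2 (799.6), Cdc20 (80.97), Derl2 (41.63), Dhcr7 (16.96), Fbln5 (278.7), Fdft1 (79.4), Fos (29.95), Gdf15 (14.81) and Mcm2 (80.9), and lowest for Cyp1a1 (39.41) and Per1 (60.81). OGD/R 1 stood highest for the interferon score (4.281), Fbln5 (105) and Slco1c1 (5.505) and lowest for oligodendrocyte markers (2.565). BD1063 3 was lowest for the hypoxia-inducible factor score (6.396) and highest for 5_8S_rRNA (11.54) and Ulk1 (40.97), and BD1063 4 was highest for the Wnt score (4.99) and lowest for choroid plexus markers (3.642). Single values stood apart in normoxia 1 (Itgax, 18.28), normoxia 3 (TGF-beta score, 6.238), OGD/R 2 (Il6, 1.355), OGD/R 6 (Depp1, 3.249), BD1063 1 (Stip1, 184.1) and BD1063 6 (Gbp2, 109.3). In DMT 2 these were Ccl2 (28.31) and Gbp2 (91.75), and in DMT 4 Fdft1 (107.5) and Slc7a5 (58.58).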

How the results depend on the processing

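The alternatives that left out several libraries together were chosen after the results were seen, as were the recovered reads and the protein-coding genes, and the others were planned. Where no cause is given below, the cause was not tested. Of calls of named genes under settings other than single libraries left out, 1071 were the same and 94 lost the threshold in OGD/R against normoxia, 248 and 82 in DMT against OGD/R, and 478 and 135 in BD1063 against OGD/R, and no named gene called in either fit turned its direction. With single libraries left out these were 920 and 21, 184 and 58, and 315 and 183. Of list calls under the other settings, 192 were the same and 32 lost in OGD/R against normoxia, 114 and 12 in DMT against OGD/R, and 108 and 18 in BD1063 against OGD/R. In BD1063 against DMT 41 were the same, 26 lost and 3 turned (36, 18 and 1 with single libraries left out).

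For DMT against OGD/R (68 genes) DESeq2 called 264, voom with sample weights 729, the fit with no low-count filter 37, the replicate block 37, the test against a fold of 1.5 0, both log2(deposited CPM) scales 5, and the fit of the 2 groups 4. Without OGD/R 5 and DMT 5 it was 458, without these and OGD/R 3 453, and without OGD/R 5, DMT 5, normoxia 3 and normoxia 5 1363. With single libraries left out it ran from 26 (without OGD/R 6) to 1083 (without DMT 5). For BD1063 against DMT DESeq2 called 1, and 0 genes were called by edgeR with single libraries left out (1005 at an unadjusted p under 0.05 with all).

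For BD1063 against OGD/R (735 genes) DESeq2 called 1297, voom 1650, no filter 257, the fold of 1.5 0, log2(deposited CPM + 0.1) 487, the 2 groups alone 1500, and the 3 sets of left-out libraries, in the order above, 1475, 1471 and 2376. Single libraries left out gave 76 to 975. The fold of 1.5 left 285 genes in OGD/R against normoxia, 173 in DMT against normoxia and 257 in BD1063 against normoxia. For DMT against normoxia the scales log2(deposited CPM + 1) and + 0.1 gave 2099 and 2058, and voom gave 5886 for BD1063 against normoxia. Single libraries left out gave 4153 to 5250 in OGD/R against normoxia, 2696 to 3489 in DMT and 3134 to 3573 in BD1063 against normoxia.

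The 49 genes called in opposite directions by OGD/R and by DMT were 195 in DESeq2, 565 in voom, 25 with no filter, 26 with the replicate block, 0 at a fold of 1.5, 340, 328 and 1091 with the sets of libraries left out, 2 on both deposited CPM scales and 12 in the fit of the 3 groups. With single libraries left out they ran from 15 to 803.

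Among list medians that turned between BD1063 and DMT were those of basement membrane genes, at -0.0437 (voom), -0.0382, -0.045 and -0.045 (sets of libraries left out) and -0.0459 (without DMT 5; up to 0.0507 with other single libraries left out), each passing camera when turned (adjusted p from 0.0111 to 0.0451), and of oxidative phosphorylation genes, at 0.0234, 0.0166 and 0.0166 (sets) and 0.0161 (without DMT 5; down to -0.2426 with others). On log2(deposited CPM + 1) and + 0.1, where the median of all genes was 0.0904 and 0.1005, the medians of interferon (0.0185 and 0.019), unfolded protein (0.0337 and 0.0339) and lysosomal genes (0.0423 and 0.0432) were positive. In DMT against OGD/R the median of mitochondrially coded transcripts was near 0, and 0.1766 without DMT 5, 0.1359 in voom and 0.1783, 0.1731 and 0.1808 in the sets, passing camera in the last.

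Replicate numbers did not pair the libraries as a whole. Residual profiles of libraries with the same number in different groups had a median correlation of 0.011 over 33 pairs (-0.345 to 0.58), against -0.01 over 165 other pairs, and 6 of 23 libraries matched best with their own number. Normoxia 5, OGD/R 5 and DMT 5 correlated at 0.415 to 0.58, but with BD1063 5 at -0.182, -0.177 and -0.345. Pairs of other numbers reached 0.492. The test found 65.7% to 74.6% of simulated 1.5-fold changes and fewer of smaller ones. Few genes were changed in these counts, so the shares need not hold in comparisons with many changed genes. Genes were drawn independently there, without shifts shared within a library. Small changes in single genes thus go partly unseen.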

Other observations

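Itgax and Cyp26b1 were chosen after their values were seen. Itgax, an integrin gene mostly known from leukocytes, rose after OGD/R from 15.4 ± 1.52 CPM in normoxia (n = 6) to 49.4 ± 4.28 CPM (n = 6; log2 fold change 1.68 ± 0.08, adjusted p = 1.34e-12), while the list of microglia and leukocyte markers did not pass (camera adjusted p = 0.291). Cyp26b1, which breaks down retinoic acid, rose from 68.5 ± 8.38 to 174 ± 18.7 CPM (1.35 ± 0.09, adjusted p = 5.48e-11). Neither passed between DMT and OGD/R (adjusted p = 0.0881 and 0.954).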
